A study of Rattus norvegicus with 6 samples.

How the data were processed

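Total RNA from the livers of 6 male Sprague-Dawley rats, 3 given corn oil and 3 given bromodichloromethane, was labelled with Cy3 and hybridised to 1-colour Agilent arrays, 1 array per animal, per the labels' protocols. The labels describe separate animals. The scans were quantified with Agilent Feature Extraction 10.7, per the submitters' processing notes and the file headers. The deposited scanner files hold linear fluorescence intensity values per spot. The processed intensity is background-subtracted, per the file headers, and is not scaled between arrays. A deposited value table of the series holds a linear ratio, which from the values is the processed signal of an array divided by its 75th percentile; at least 96.3% of the probes of every array lay within 1% of that relation. Its columns are not centred per gene, have medians between 0.0954 and 0.102, and were used only as an alternative. No statistical method of the authors is given in the sources used here.

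Each array has 62976 spots, of which 1319 are controls. Spots marked as non-uniform or as outliers on any array were left out, which removed 27 probes. Processed intensities were taken to log2, and the 75th percentile over non-control probes of each array was subtracted. The files hold a probe name and an accession but no gene symbol, so probes were named by matching unversioned accessions to NCBI RefSeq transcripts of the rat assembly GRCr8, which is a later build than the one in the file headers and was used for names only. Of 61657 probes, 27460 (44.5%) matched 1 symbol, 0 matched several and 34197 matched none; the last kept their accession, were tested, and are counted but not named here. The array carried 15284 distinct symbols. No coordinates are given because no genome of the arrays' build was used here.

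A probe was kept when it was well above background on all 3 arrays of at least 1 group. For each symbol or accession the probe with the highest mean normalised signal over the 6 arrays stood for the gene, which left 28995 features. Groups were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes without trend or robust options, two-sided, with Benjamini-Hochberg adjustment over all features; the threshold was an adjusted p of 0.05, with a second count at 2-fold. Every adjusted p of a gene comes from that model, and SE is the moderated standard error of the log2 fold change. Where a probe was not well above background on any array of one group, the fold is a lower bound. It is the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the lowest signal well above background and the probe's own signal.

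The 42 gene lists, the settings of the test and most alternatives were fixed before the data were examined. The lists hold 1215 entries, of which 1109 were on the array and 1044 were measured. Lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Genes named were the 10 largest rises and 10 largest falls by fitted change past the threshold with non-overlapping groups and a gene symbol, 8 genes fixed in advance, and for each list up to 4 members past the threshold with the largest change, or the 2 with the smallest p where none passed. Of the first 20, the fitted changes of Trim54, Gucy2c, Gpat3, Or7a44 and Mst1r rest on signals not well above background in 1 group, so these 5 are given as bounds without rank; among genes measured in both groups Acot1 and Car3 came next. The rule gave 129 distinct genes, of which those in the text are a part; genes outside it are named as chosen after their values were seen. The result of 1 such gene is not reported here.

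The model was tested on simulated data made from the means and residual spread of the 28995 real features, with 200 genes changed in each of 5 runs. It recovered 10.7% of genes changed 1.5-fold, 52.2% of those changed 2-fold and 86.1% of those changed 4-fold, and 4.81% of its calls were false. A list of ribosomal protein genes shifted by 0.3 was found by camera in 5 of 5 runs with 0 other lists called. Far fewer genes were changed per run than the 2715 features called in the data, so a call in these runs needed a smaller unadjusted p. Residual spreads were also shuffled between features. The recovered shares are therefore no estimate of the sensitivity of the real comparison. The simulated noise was independent between genes. These runs therefore cannot show how often camera falsely calls lists whose genes move together between animals.

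The alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, no filter and a stricter filter on dim probes, the mean over the probes of a gene, every probe on its own, eBayes with trend and robust options, array weights, the authors' value table, slide as a fixed or random block, slide 1 alone, the replicate number as a block, and leaving out each animal in turn. The planned normexp setting was to use mean signals, which the files do not hold, so median signals were used. Chosen after seeing the data were that change, a fit on features with symbols only, a common floor, and scaling by the spiked-in control transcripts. Slides and scans were numbered from the file headers. Figures were drawn with matplotlib.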

Results

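Liver RNA from 6 male Sprague-Dawley rats was measured on 1-colour Agilent microarrays, with 1 array per animal. Of these animals, 3 received corn oil, the vehicle, and 3 received bromodichloromethane at 200 mg/kg/day. Bromodichloromethane is a trihalomethane that forms when drinking water is chlorinated, and the series asks how a chemical changes gene expression in rat liver. The rats were purchased at 5 weeks of age. The labels give 28 days as the time of measurement in one place and 9 weeks of administration in another, and the length of exposure is therefore not settled here.

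Each array carried 61657 non-control probes. The 75th percentile of the processed signal lay between 670 and 825 fluorescence units, no non-control probe was saturated on any array, and between 61.3% and 66.9% of the probes were well above background. That share was 62.5% ± 1.34 (SD, n = 3) in corn oil livers and 66.0% ± 0.788 (SD, n = 3) in treated livers. The number of arrays limits the precision. The 3 corn oil arrays and treated replicate 1 lay on slide 1, and treated replicates 2 and 3 lay on slide 2, which was scanned separately. Across features, the 3 corn oil arrays on slide 1 had Pearson correlations of 0.989 to 0.991 with each other, while corn oil arrays and treated replicate 1 on that same slide had correlations of 0.981 to 0.982; features are not independent replicates. The first principal component held 50.5% of the variance and separated the groups, with treated replicate 1 at 43.7 beside its group mates at 45.3 and 38.3, and the corn oil arrays at -43.4, -47.1 and -36.9.

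**Figure D1:**
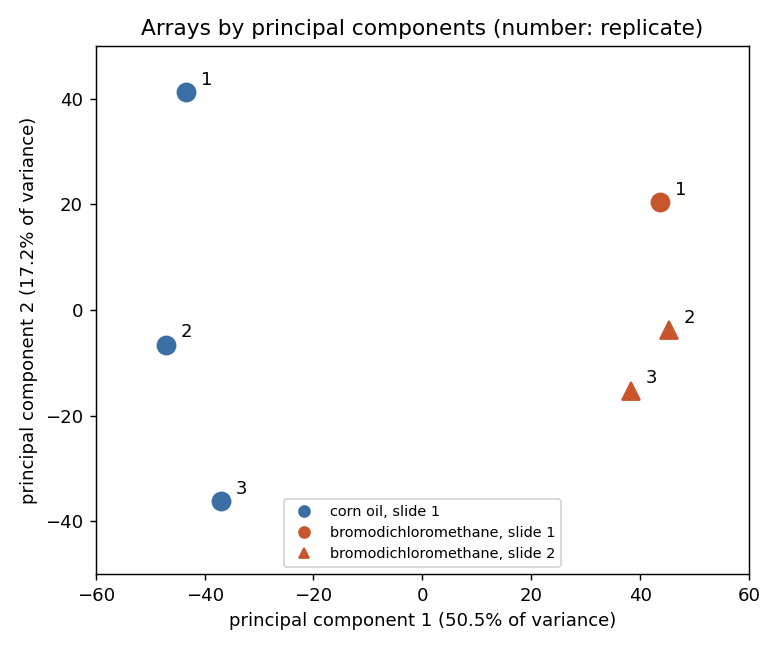
Scores of the 6 liver arrays on the first (x axis, 50.5% of variance) and second (y axis, 17.2% of variance) principal components of normalised log2 signals, in arbitrary units. Each point is 1 animal, colour gives the group, shape gives the slide and the number gives the replicate; the 3 treated animals sit between 38.3 and 45.3 on the first component, whichever slide they were on.

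In treated livers, the efflux pump gene Abcc3, the aldo-keto reductase genes Akr1b7 and Akr1b8 and the glutathione peroxidase gene Gpx2 were among those with the largest rises, and liver genes that are more abundant in males were lower as a list. The camera call of that list, made at a preset inter-gene correlation, did not hold with an estimated correlation (adjusted p = 0.27). Of 28995 features tested with limma, 2715 passed an adjusted p of 0.05, with 1727 higher and 988 lower in treated livers, and 676 of them differed by at least 2-fold, with 375 higher and 301 lower. Of the 11405 features with a gene symbol, 903 passed, with 477 higher and 426 lower. The values of the groups did not overlap for 34.4% of features, where chance gives 10%. The group of treated animals held 1 array on slide 1, and with slide as a block, which then estimates the treatment effect from that array alone, 350 features passed; within slide 1 alone 120 passed, and all 2715 features kept their direction in both fits. Treated replicate 1 took part in the main calls. Directions kept in fits that rest on that array are therefore no independent check on the slide. Leaving out 1 animal also lowered the count, to 1232, 461 and 1060 without corn oil replicates 1, 2 and 3, and to 1171, 335 and 749 without treated replicates 1, 2 and 3. Of the 92 named genes that passed, all kept their direction on slide 1 alone, 26 passed with slide as a block, 28 passed in each of the 6 fits that left out 1 animal, and between 32 and 64 passed in any one of those fits. All 92 also kept their direction with normexp background correction, with slide as a block and with a common floor under dim signals, but the fold of 27, 19 and 11 of them moved by more than 1.5 times, and without the filter on dim probes 43 passed. Median centring in place of the 75th percentile moved the share of higher calls from 63.6% to 74.2%, and scaling by the spiked-in control transcripts, an alternative chosen after seeing the data, moved it to 97.6% because it shifted the median of all features upwards to 0.48 on the log2 scale. Fold changes are therefore relative to the 75th percentile of each array, and a fall smaller than about that shift is a fall relative to the other transcripts.

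Among the largest rises, Abcc3, an efflux pump for glucuronide and bile acid conjugates, was 21.6-fold higher in treated livers (log2 fold change 4.43, SE 0.13, adjusted p = 0.00052), and it was higher in each of the 3 treated animals than in any corn oil animal. The aldo-keto reductases Akr1b7 and Akr1b8 rose by 5.89 (SE 1.19) and 4.31 (SE 0.64) on the log2 scale. Akr1b7 was well above background in only 1 corn oil animal, corn oil replicate 3, and only a bound would hold without that animal. Its log2 fold change was 5.18 with a common floor under dim signals, 5.19 without corn oil replicate 2, and 6.75 and 5.12 without treated replicates 1 and 3. Its call stood without corn oil replicate 3 (adjusted p = 0.034) and ended when any one of the other 5 animals was left out (adjusted p from 0.052 to 0.11). Akr1b8 was at 3.52 without treated replicate 2. Gpx2, a glutathione peroxidase, rose by 3.82 (SE 0.67), or 3.19 without corn oil replicate 3. Mmp12, the macrophage elastase, rose by 4.39 (SE 0.37) and was well above background in 2 of the 3 corn oil animals; with normexp it was at 2.59. Prlr, the prolactin receptor, rose by 3.74 (SE 0.49), and Grin2c, a glutamate receptor subunit, by 3.68 (SE 0.42). For 3 more genes the corn oil signal was not well above background on any array, so that only a bound and no rank holds. Trim54 was at least 7.74-fold higher, Gucy2c, a guanylate cyclase, at least 6.26-fold higher, and Gpat3, a glycerol-3-phosphate acyltransferase, at least 3.17-fold higher (adjusted p = 0.0017, 0.010 and 0.0082). With the common floor, the highest of the 6 arrays' lowest signals well above background, their log2 fold changes were 2.76, 2.45 and 1.47, and the call of Gpat3 ended (adjusted p = 0.079).

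The largest falls were led by Dhrs7l1, a gene of the short-chain dehydrogenase family, with a log2 fold change of -7.02 (SE 0.43, adjusted p = 0.0025). Inmt, an N-methyltransferase of indoleamines, followed at -6.69 (SE 0.67); it was well above background in 2 of the 3 treated animals and stood at -5.96 without treated replicate 3. Cdh17, a cadherin, was at -5.94 (SE 0.59), Zfp37 at -4.09 (SE 0.41), Fmo1, a flavin-containing monooxygenase, at -3.79 (SE 0.72), Kcnip1 at -3.71 (SE 0.32), Acnat2, an acyl-CoA amino acid acyltransferase, at -3.70 (SE 0.21) and Chrnb2 at -3.69 (SE 0.35). With normexp Zfp37, Kcnip1 and Chrnb2 were at -2.65, -2.46 and -2.68. Fmo1 was at -4.61 without treated replicate 1, and at -3.09 with its call ended (adjusted p = 0.074) without treated replicate 2. The signals of Or7a44, an olfactory receptor gene, and Mst1r, the receptor of macrophage-stimulating protein, were not well above background in any treated animal, and the genes were at least 14.5-fold and at least 3.38-fold lower. With the common floor they were at -3.07 and -0.97 on the log2 scale and both calls ended (adjusted p = 0.060 and 0.11). The bound of Or7a44 rests largely on corn oil replicate 1, and was at least 7.90-fold without that animal and at least 22.4-fold without corn oil replicate 2.

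**Figure D2:**
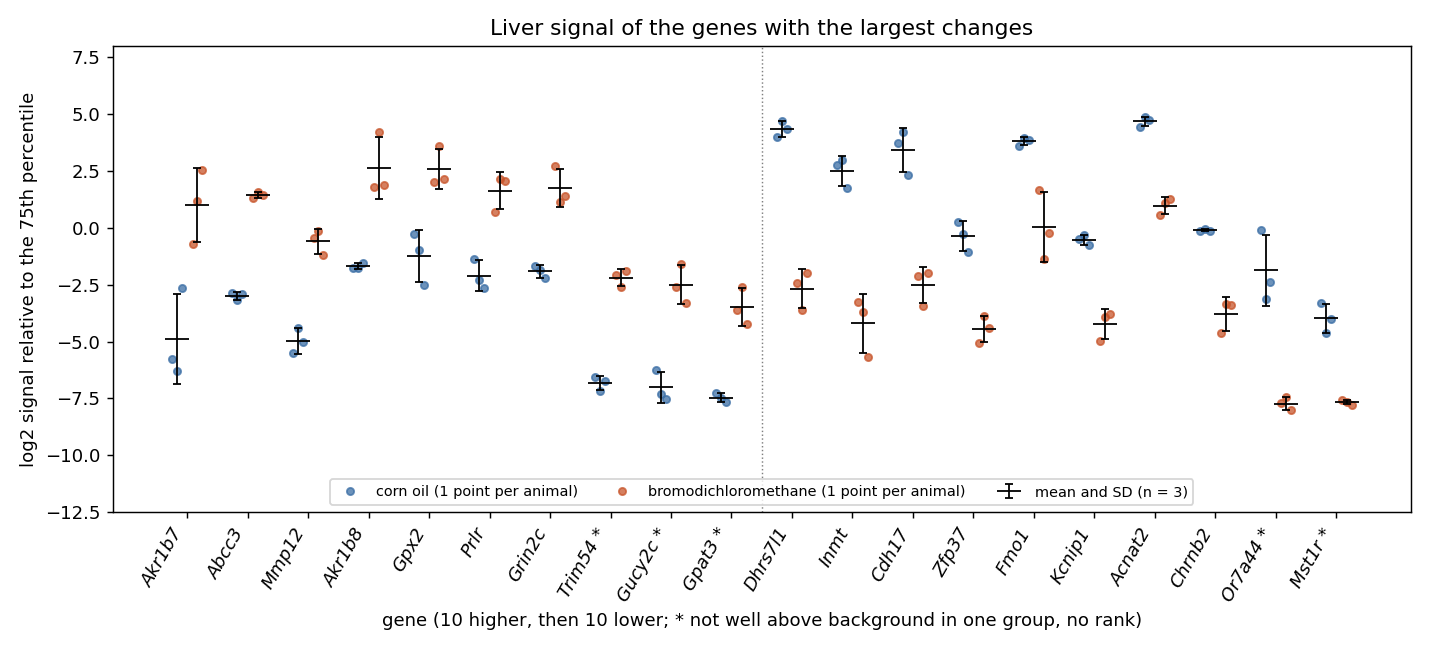
Normalised log2 signal relative to the 75th percentile of the array (y axis) of the 10 genes higher and the 10 genes lower that the fixed rule took by their fitted change (x axis). Genes with an asterisk stand last on their side because they were measured in 1 group only and have no rank. Each point is 1 animal and the black marks are the mean and SD (n = 3 per group); the groups do not overlap for any of these genes, and Trim54, Gucy2c and Gpat3 in corn oil livers and Or7a44 and Mst1r in treated livers were not well above background.

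Genes fixed for the comparison because of their part in the handling of halogenated methanes or in liver injury gave mixed results. Gstp1, the placental glutathione S-transferase, was 6.95-fold higher (log2 fold change 2.80, SE 0.47, adjusted p = 0.024), whereas Gstt1, a theta-class transferase that acts on small halogenated compounds, stood at 0.22 (SE 0.22) and did not pass (adjusted p = 0.56). Cyp1a2 fell by 1.31 on the log2 scale (SE 0.21, adjusted p = 0.021), and Cyp2b1 stood at -0.44 (SE 0.10, adjusted p = 0.044) but at 0.04 with spike-in scaling. Cyp2e1, the main P450 of low-dose haloform oxidation, was at -0.23 (SE 0.25, adjusted p = 0.60) and at 0.23 on slide 1 alone, so that no direction can be given. Cyp3a23-3a1 at 0.05, Hmox1 at 0.16 and Cdkn1a at -0.28 did not pass either (adjusted p = 0.79, 0.56 and 0.17).

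Among 42 gene lists fixed before the data were examined, 6 were higher and 11 were lower by limma's camera with a preset inter-gene correlation of 0.01 and adjustment over the 42 lists. With a correlation estimated for each list none of the 17 calls held, and those adjusted p-values are given beside each list. Fry, which tests whether a list's genes move one way on balance without comparing them with other genes, kept 8 of the 17. With slide as a block 11 of the 17 calls held and within slide 1 alone 14 held, and the direction of all 17 was the same in both; list medians on slide 1, which are identical with slide as a block, are given as the slide 1 median.

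NRF2 target genes, which encode enzymes of detoxification and glutathione supply, were higher as a list (adjusted p = 5.3e-08, and 0.27 with an estimated correlation). Of 42 measured members 18 rose, none fell and 24 did not pass, and 23 rose when adjusted over the list alone. The median log2 fold change was 0.49, and 0.48 on slide 1. Akr1b7, Abcc3, Akr1b8 and Gpx2 had the largest rises, and Nqo1, the quinone oxidoreductase, rose by 0.71 (SE 0.15, adjusted p = 0.038). The list of fetal liver and preneoplastic focus genes, which shares Abcc3, Akr1b8 and Gpx2 with it, had 9 members higher, 1 lower and 13 not past, against 10 higher and 3 lower when adjusted over the list alone (list adjusted p = 0.023, and 0.27 with an estimated correlation). Its median was 0.16, 0.38 on slide 1 and 0.10 with normexp, the call ended with spike-in scaling (adjusted p = 0.42), and the member that fell was Cdh17. Glutathione S-transferases went both ways, with 5 higher and 2 lower of 22, and the same numbers when adjusted over the list alone. Mgst2 rose by 0.89 while Gstm6 and Gstm7 had log2 fold changes of -1.19 and -1.10, and the list did not pass (adjusted p = 0.25).

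Cytosolic ribosomal protein genes were higher as a list by a small and even amount (adjusted p = 1.3e-19, and 0.53 with an estimated correlation). All 70 measured members had a log2 fold change above 0, with a median of 0.36, and 0.41 on slide 1. Of these, 23 passed on their own and 59 when adjusted over the list alone. Rps19 rose by 0.71 (SE 0.11), Rpl23a by 0.69 (SE 0.10), Rpl12 by 0.63 (SE 0.10) and Rps26 by 0.61 (SE 0.09). Oxidative phosphorylation genes had a median of 0.02 and proteasome genes of -0.004, and neither list passed (adjusted p = 0.87 and 0.90).

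Liver genes that are more abundant in male than in female rats were lower as a list (adjusted p = 5.3e-08, and 0.27 with an estimated correlation). All 16 measured members had a log2 fold change below 0, with 6 past the threshold and 12 when adjusted over the list alone, and the median was -0.83, -0.78 on slide 1 and -0.35 with spike-in scaling. Cyp2c11, the main male-specific P450 of rat liver, was 8.15-fold lower (log2 fold change -3.03, SE 0.37, adjusted p = 0.012). The major urinary protein genes Mup4 and Mup5 had log2 fold changes of -2.82 (SE 0.37) and -2.26 (SE 0.34), and the transporter gene Ust5r of -1.98 (SE 0.21). Female-biased genes did not pass as a list (adjusted p = 0.15), with 3 of 17 higher and 3 lower, and 7 and 3 when adjusted over the list alone. Prlr and the sulfotransferase Sult2a6, at 2.97 (SE 0.64), were among those that rose, and Fmo1 and Abcg8, a sterol transporter at -1.71 (SE 0.34), were among those that fell. Membership follows the fixed list, and with male animals only, the sex bias of single members could not be checked.

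Lists of secreted and metabolic hepatocyte genes fell relative to the other transcripts, by medians that lay above 0 with spike-in scaling. Complement and coagulation genes had 12 of 37 members lower and none higher, with 27 lower when adjusted over the list alone (list adjusted p = 4.5e-13, and 0.34 with an estimated correlation). Their median was -0.41, -0.47 on slide 1 and 0.07 with spike-in scaling. A2m, a protease inhibitor, had the largest fall at -2.33 (SE 0.47), and Mbl2 followed at -0.70 (SE 0.10). Urea cycle and amino acid genes had 9 of 38 members lower and none higher, with 20 lower when adjusted over the list alone (list adjusted p = 4.6e-09, and 0.27 with an estimated correlation). Their median was -0.48, -0.28 on slide 1 and 0.0062 with spike-in scaling. Oat, the ornithine aminotransferase, was 7.56-fold lower (log2 fold change -2.92, SE 0.29), and Gnmt, a glycine methyltransferase, and Cps1, the first enzyme of the urea cycle, were at -0.93 (SE 0.15) and -0.62 (SE 0.11). Acute phase genes had 5 of 30 lower and none higher, and 6 lower and 1 higher when adjusted over the list alone (list adjusted p = 0.00089, and 0.56 with an estimated correlation). Their median was -0.25, -0.33 on slide 1 and 0.23 with spike-in scaling, and after quantile normalization it was -0.01 and the call ended (adjusted p = 0.31).

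Bile acid genes had 5 of 27 members lower and 2 higher, and 13 lower and 2 higher when adjusted over the list alone (list adjusted p = 0.0011, and 0.27 with an estimated correlation). The median was -0.42, -0.33 on slide 1 and 0.06 with spike-in scaling, and with slide as a block the call ended (adjusted p = 0.053). Amacr and Acox2, enzymes of bile acid side-chain shortening, had log2 fold changes of -1.14 (SE 0.22) and -1.02 (SE 0.13), while Abcc3 was the member with the largest rise. Genes of pericentral and of periportal hepatocytes, the opposite ends of the liver lobule, were both lower as lists (both adjusted p = 0.0035, and 0.51 and 0.27 with an estimated correlation). Both share members with lists given above. Cyp2c11 is a pericentral and a male-biased gene, and the urea cycle and amino acid list shares Oat with the pericentral list and Cps1 with the periportal list. Pericentral genes had 6 of 21 lower and 1 higher, with 9 and 2 when adjusted over the list alone, and a median of -0.33, -0.38 on slide 1 and 0.15 with spike-in scaling. Slc1a2, a glutamate transporter, was at -3.36 (SE 0.68), at -4.13 without treated replicate 1 and at -2.76 (adjusted p = 0.092) without treated replicate 2. Periportal genes had 3 of 20 lower and none higher, with 5 lower when adjusted over the list alone, and a median of -0.31, -0.31 on slide 1 and 0.18 with spike-in scaling; Arg1 and Otc of the urea cycle were at -0.54 (SE 0.08) and -0.53 (SE 0.08). With slide as a block neither zonal list passed (adjusted p = 0.053 for pericentral and 0.063 for periportal genes), nor did either without the filter on dim probes (both 0.065), and on slide 1 alone the periportal list did not (0.071).

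Another 3 metabolic and stress lists were lower, with few members past the threshold. Gluconeogenesis and glycogen genes had 3 of 24 lower, and 6 when adjusted over the list alone, with Pfkfb1 at -1.18 (SE 0.22) and Ppp1r3b at -1.03 (SE 0.23) (list adjusted p = 0.021, and 0.27 with an estimated correlation). Cholesterol genes had 1 of 28 lower, Sc5d at -0.73 (SE 0.15), and 0 when adjusted over the list alone (list adjusted p = 0.0040, and 0.56 with an estimated correlation). Unfolded protein and integrated stress response genes had 1 of 33 lower, and 0 when adjusted over the list alone (list adjusted p = 0.0062, and 0.56 with an estimated correlation). The medians of the 3 lists were -0.21, -0.21 and -0.31, on slide 1 -0.33, -0.05 and -0.53, and with spike-in scaling 0.27, 0.27 and 0.17. The cholesterol call ended with slide as a block (adjusted p = 0.23), on slide 1 alone (0.24), without the filter on dim probes (0.098) and without treated replicate 3 (0.073). The gluconeogenesis call ended with slide as a block (0.081), on slide 1 alone (0.090), without the filter (0.24) and with normexp (0.067), and the stress response call without the filter (0.24), corn oil replicate 3 (0.062) or treated replicate 1 (0.068).

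Inflammatory mediators, macrophage markers and T and NK cell markers were higher as lists. Inflammatory cytokine and chemokine genes had 7 of 31 higher and none lower, and 11 higher and 1 lower when adjusted over the list alone (list adjusted p = 0.0029, and 0.53 with an estimated correlation), with a median of 0.33, 0.27 on slide 1 and 0.19 with normexp. Ccl2, a monocyte chemoattractant, was 6.16-fold higher (log2 fold change 2.62, SE 0.37, adjusted p = 0.017), Ccl7 was at least 2.51-fold higher (log2 fold change 1.13 with the common floor), Tnf rose by 1.65 (SE 0.28) and Il1b by 1.06 (SE 0.16). Macrophage markers had 6 of 26 higher and none lower, and 7 higher when adjusted over the list alone (list adjusted p = 0.0035, 0.053 with slide as a block, and 0.53 with an estimated correlation). Their median was 0.17, and 0.16 on slide 1, and Trem2 rose by 2.03 (SE 0.28), Gpnmb by 1.73 (SE 0.36) and Cd74 by 0.88 (SE 0.14). T and NK cell markers had 3 of 23 higher and none lower, and 4 when adjusted over the list alone (list adjusted p = 0.00089, and 0.53 with an estimated correlation). Their median was 0.35, 0.34 on slide 1, 0.15 with normexp and 0.28 with 3 dim members at their bound; Cd8b rose by 0.86 (SE 0.14), and Cd2 and Cd3e were at least 1.47-fold and at least 1.33-fold higher. Both calls ended with the common floor (log2 fold change 0.36 and 0.23, adjusted p = 0.29 and 0.30) and with normexp (0.23 and 0.099, adjusted p = 0.13 and 0.50). Red blood cell genes were lower as a list, with all 11 members below 0, 1 of them past the threshold both over all genes and when adjusted over the list alone (list adjusted p = 0.0037, and 0.53 with an estimated correlation). Their median was -0.39, -0.69 on slide 1 and 0.10 with spike-in scaling, and Epb42, a red cell membrane protein gene, was at -1.68 (SE 0.34), well above background in 2 of the 3 treated animals, and at -0.62 with normexp. Without the filter on dim probes the list call ended (adjusted p = 0.12). Markers of the other 9 cell types did not pass, among them endothelial cells (median -0.14, adjusted p = 0.33), stellate cells and fibroblasts (-0.02, 0.84), cholangiocytes (0.12, 0.20), B and plasma cells (0.09, 0.90), neutrophils (0.23, 0.26) and proliferating cells (0.17, 0.17), as well as pancreas (0.03, 0.92), kidney (-0.21, 0.26) and adipose tissue (-0.08, 0.90). Cholangiocyte markers still had 3 of 17 members higher and none lower, Ggt1 among them, and endothelial markers 2 of 17 higher and 1 lower. Adipose tissue had 1 of 10 higher and 1 lower, pancreas 1 of 10 higher, and B and plasma cells 1 of 11 lower. The rest had none past the threshold.

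Some lists that did not pass held members that rose. Of 25 target genes of the xenobiotic receptors CAR and PXR 8 were higher and 2 lower, or 9 and 5 when adjusted over the list alone (list adjusted p = 0.12), with Akr7a3 at 2.34 (SE 0.38) and Cyp3a9 at -2.10 (SE 0.17). That list did pass with fry (adjusted p = 0.010), normexp (0.030), no filter on dim probes (0.0064), every probe on its own (0.0062) and without corn oil replicate 1 (0.029). Of 43 PPAR-alpha target genes 5 were higher and none lower, and 5 when adjusted over the list alone (list adjusted p = 0.63), with the acyl-CoA thioesterases Acot1 and Acot2 at 3.36 (SE 0.18) and 1.16 (SE 0.13). Of 37 interferon response genes 6 were higher and none lower, and 8 when adjusted over the list alone (list adjusted p = 0.16), with Cxcl10 at 1.82 (SE 0.21), Ifi47 at 1.59 (SE 0.20) and Irf1 at 1.24 (SE 0.21). Of 29 fatty acid and triglyceride synthesis genes 5 were higher and none lower, or 7 and 2 when adjusted over the list alone (list adjusted p = 0.44), with Elovl6, a fatty acid elongase, at 2.08 (SE 0.21). Of 29 p53 target genes 3 were higher and 1 lower, or 5 and 3 when adjusted over the list alone (list adjusted p = 0.92), with Fas at 1.34 (SE 0.15) and Bbc3 at 0.61 (SE 0.11). The remaining lists did not pass, though most held members past the threshold. Glucuronosyl- and sulfotransferases (adjusted p = 0.87) had 4 of 18 members higher and 2 lower. Circadian clock genes (0.87) had 2 of 16 higher and 2 lower, and extracellular matrix genes (0.51) 1 of 25 higher and 3 lower. AHR targets (0.78) had 1 of 5 higher and 1 lower, and haem genes (0.93) 1 of 17 higher and 1 lower. Heat shock proteins (0.26) and metallothionein, iron and zinc genes (0.90) had none past the threshold. In 9 of the 25 lists that did not pass, the mean, the median and the direction of the test differed in sign.

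**Figure D3:**
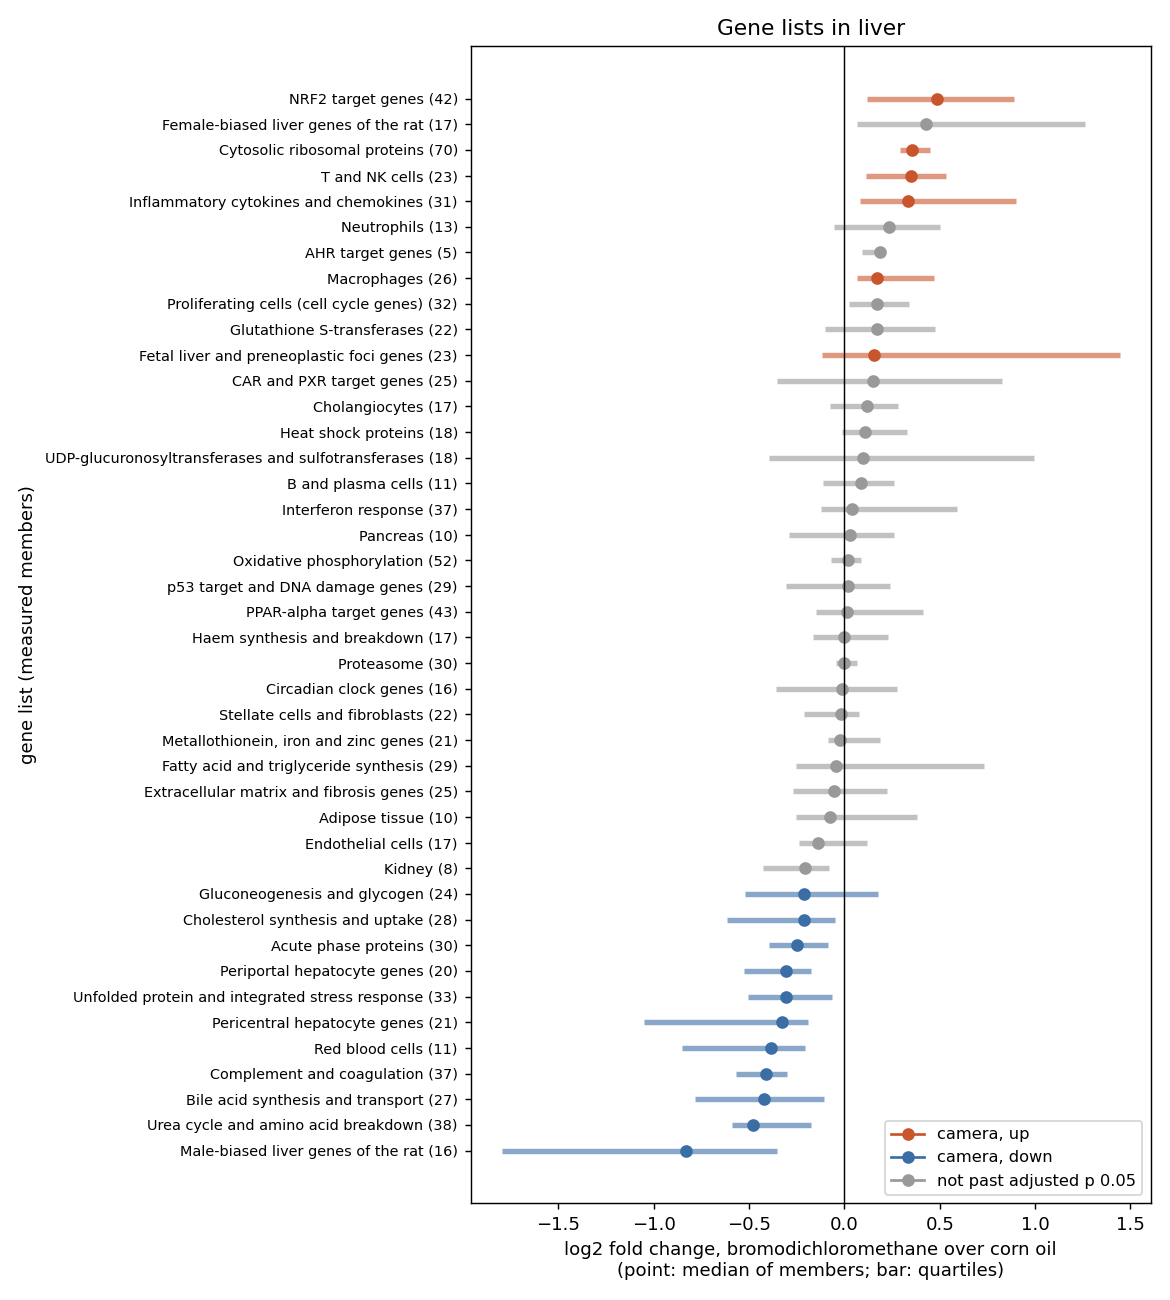
Median log2 fold change of bromodichloromethane over corn oil livers (x axis; bars are the quartiles over members, not errors of the median) for the 42 gene lists (y axis, with the number of measured members). Colours give the direction of the 17 lists past an adjusted p of 0.05 by camera with the preset correlation; male-biased genes have the lowest median (-0.83) and NRF2 target genes the highest (0.49), and with spike-in scaling 10 of the 11 medians of the lists that fell lie above 0. With a correlation estimated for each list none of the 17 passes.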

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

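Chosen after seeing the data were normexp on median signals, the fits on features with symbols and with a common floor, and the spike-in scaling; the other alternatives were planned. The 2715 features past the threshold kept their direction wherever they were tested one value per gene, except that 2712 did with normexp, 2710 with the mean over probes and 2545 with spike-in scaling. Counts that moved by more than 1.5 times, followed by those at 2-fold, were 609 and 383 with no filter on dim probes (45862 features tested), 4126 (848 at 2-fold) with array weights, 350 and 334 with slide as a fixed block, 120 and 120 on slide 1 alone, 924 and 280 of 11405 features with symbols, and 12996 and 2699 with spike-in scaling, while normexp gave 428 at 2-fold. Leaving out 1 animal gave 335 to 1232 features and 258 to 557 at 2-fold. The group labels share replicate numbers, but these name different animals, so the samples were not treated as paired. The deviations of equal numbers correlated at 0.092, 0.019 and 0.12. Every sample correlated best with its own number, a hint from the data and not the design. With the replicate number as a block 353 features passed, 308 of them at 2-fold, and all 17 list calls were kept. Of the 42 lists, 11 passed with slide as a fixed block, 0 with an estimated correlation and 9 with fry, and 16 to 20 passed in the other alternatives except slide 1 alone (14). These counts include lists not called in the main fit: without the filter on dim probes 19 passed but only 11 of the 17 main calls were kept, while fry kept 8 and the other alternatives with 16 to 20 lists kept 16 or 17. Beside CAR and PXR targets, uncalled lists that passed in more than 1 alternative were interferon response (5), female-biased (3), glutathione S-transferase, heat shock and cell cycle genes (2 each). List tests with slide as a random block, and normexp on mean signals, were not run. Of called genes whose values with normexp are not given elsewhere and that are not given as bounds, normexp moved Akr1b7 to 3.98, Abcc3 to 3.80, Slc1a2 to -2.47, Inmt to -5.23, Trem2 to 1.21, Olr1 to 1.09, Fabp4 to 1.29, Cpa3 to -0.67, Abcg8 to -1.06, Ggt1 to 1.93, Cdh17 to -5.29 and Dhrs7l1 to -6.40, with calls kept. Slide as a block moved Akr1b7 to 4.17, Akr1b8 to 3.47, Inmt to -5.75, Fmo1 to -2.13, Slc1a2 to -1.83, Prlr to 2.81, Ggt1 to 2.05, Dusp1 to -1.38 and Sult2a6 to 2.05, with calls ended, and Gstp1 to 3.93, A2m to -3.37, Cyp2c11 to -3.90, Mup4 to -3.69, Mup5 to -3.06, Zfp37 to -4.69, Chrnb2 to -4.54, Kcnip1 to -4.44, Epb42 to -2.43 and Grin2c to 4.64, with calls kept. Values that turned sign were those of the genes below, none of them called except Cyp2b1. Cyp2e1 was at 0.23 with slide as a block and on slide 1 alone, at 0.25 with spike-in scaling and between -0.47 and 0.022 when 1 animal was left out. Cyp3a23-3a1 was at -0.021 with quantile normalization, at -0.018 with array weights and between -0.025 and 0.13 when 1 animal was left out. Hmox1 was at -0.041 with slide as a block and on slide 1 alone. Fkbp5 was at 0.21 with slide as a block and on slide 1 alone, at 0.30 with spike-in scaling and between -0.49 and 0.19 when 1 animal was left out. With spike-in scaling Cyp2b1 was at 0.042, Cdkn1a at 0.21, Ddx3y at 0.34 and Eif2s3y at 0.31. The spike-in scaling raised the median of all features by its construction, which bears on its counts. Other settings differed in the number of features, samples or arrays per slide, but whether that moved their counts was not tested. For normexp, array weights and the turned signs the cause was not tested either. Signal over background limits the genes given as bounds, 130 of the 2715 features past the threshold.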

Other observations

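The lists of mast cell, glucocorticoid-induced and lipid-associated macrophage genes were chosen only after their values were seen, as were the genes named here that the fixed rule had not named, which are all but Mmp12, Trem2, Gpnmb, Fabp4, Per1, Car3 and Ggt1. The camera p-values of those lists come from the same values that led to their choice. They describe the lists and are not tests, also with slide as a block or 1 animal left out. Of 20 mast cell and basophil genes 12 were measured, 6 were lower in treated livers, none was higher and 6 did not pass. The median log2 fold change was -0.86, and -0.86 on slide 1. Fcer1a, the alpha chain of the high-affinity IgE receptor, was not well above background in any treated animal and was at least 2.17-fold lower (adjusted p = 0.024), a call that ended with a common floor (log2 fold change -0.33, adjusted p = 0.30) and with normexp (-0.41, adjusted p = 0.062). The mast cell carboxypeptidase Cpa3 was at -1.29 (SE 0.18), the tryptase Tpsab1 at -1.03 (SE 0.10), and the proteases Mcpt10 and Mcpt8 at -1.15 (SE 0.11) and -0.92 (SE 0.13). Camera gave an unadjusted p of 9.4e-07 for the list, 9.6e-07 with slide as a block, at most 1.2e-05 with 1 animal left out, and 0.029 with an estimated correlation. Of 20 lipid-associated macrophage genes 19 were measured, 9 were higher, none was lower and 10 did not pass, with a median of 0.87, and 1.18 on slide 1. Clec7a, not well above background in any corn oil animal, was at least 2.16-fold higher (adjusted p = 0.0095), or at 0.91 on the log2 scale with the common floor. Olr1, Pla2g7 and Fabp4 rose by 2.08 (SE 0.36), 2.07 (SE 0.15) and 2.06 (SE 0.16), in addition to Mmp12, Trem2, Gpnmb, Lgals3 and Cd44. Camera gave an unadjusted p of 2.1e-07, 2.1e-07 with slide as a block, at most 9.7e-07 with 1 animal left out, and 0.013 with an estimated correlation. 

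Of 22 measured genes that glucocorticoids induce, 6 were lower, none was higher and 16 did not pass, with a median of -0.49, and -0.33 on slide 1. Dusp1, a phosphatase of MAP kinases, was at -1.98 (SE 0.46, adjusted p = 0.0499), a call that ended in 13 of 22 alternatives, among them slide as a block (-1.38, adjusted p = 0.29). Pim3 was at -1.25 (SE 0.20), Tsc22d3, the glucocorticoid-induced leucine zipper, at -1.14 (SE 0.23), the clock gene Per1 at -1.05 (SE 0.10), Zfp36 at -0.98 (SE 0.18) and Ddit4 at -0.85 (SE 0.15). Fkbp5, at -0.18 (SE 0.36), and Tat, at -0.74 (SE 0.34), did not pass, and Fkbp5 turned to 0.21 on slide 1 alone. Camera gave an unadjusted p of 2.2e-05, 0.011 with slide as a block, at most 0.00034 with 1 animal left out, and 0.11 with an estimated correlation. Among other genes, Car3, carbonic anhydrase 3, was at -3.63 (SE 0.27), Slc13a5, a citrate transporter, at -2.16 (SE 0.16), and Glul, the glutamine synthetase of the pericentral rim, at -1.14 (SE 0.21), while Ggt1, gamma-glutamyltransferase 1, rose by 2.70 (SE 0.33).

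Of the tests that follow, the comparison of ribosomal protein genes with lists matched on signal was set before its result was seen, and the others were chosen after the results they bear on. The first pattern is the difference between the groups as a whole. The slide as its whole cause is argued against. Over the 1171 features called without treated replicate 1, the shift of that animal, which shared slide 1 with the corn oil animals, was a median of 0.92 times the shift of treated replicates 2 and 3 (quartiles 0.61 and 1.21), and 97.4% went the same way. The shift of treated replicate 1 was taken against corn oil replicates 2 and 3, and that of the other treated animals against corn oil replicate 1. These corn oil animals also took part in calling the features, which favours agreement. The ratio rests on 1 treated animal, and how much slide 2 added to the shift of the other 2 treated animals stays open. The 6 arrays can be split into 3 and 3 in only 10 ways, too few for a share under 0.05; the real split gave 2715 features, 1 of the 10 splits gave as many, and the highest other gave 2.

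The second pattern is the fall of male-biased genes. If a lower share of hepatocytes were its whole cause, other hepatocyte genes would fall as far, but the median of the 16 male-biased genes minus that of 75 complement, coagulation, urea cycle and amino acid genes was -0.41 (one-sided permutation test over genes, p = 2e-05). That test shuffles genes as if they were independent, so its p holds no spread between animals. The low median of the male-biased list was known when the test was chosen. The comparison did not separate zones of the lobule. It therefore does not bear on a loss limited to pericentral hepatocytes, whose list shares Cyp2c11. With an estimated correlation the male-biased list itself did not pass (adjusted p = 0.27). A mix-up of sexes is argued against by the Y-linked genes Ddx3y and Eif2s3y, whose mean log2 fold change was -0.16 (0.34 and 0.31 for the genes with spike-in scaling), with both well above background in all animals. Changed regulation of sex-biased genes in hepatocytes may remain, as a hypothesis that no test here addressed. A part played by a loss of pericentral hepatocytes, body weight, feeding or slide also stays open.

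The third pattern is the even rise of ribosomal protein genes. A brighter reading of all abundant transcripts on treated arrays is argued against, since the median of the ribosomal list (0.36) lay above that of 100% of 10000 random lists matched on mean signal, whose highest median was -0.01. RNA quality that favours short, stable transcripts stays open. The comparison used oxidative phosphorylation genes, which were assumed to be as short and stable, with both list medians already known. No value of transcript length or RNA integrity was used. The oxidative phosphorylation genes lay 0.34 below the ribosomal genes (one-sided permutation test over genes, p = 1e-05, the smallest that 100000 permutations can give). That p treats genes as independent and holds no spread between animals. The ribosomal protein genes move together from animal to animal, with an estimated inter-gene correlation of 0.75, so that 3 animals per group leave chance variation of the whole list between animals open (adjusted p = 0.53). A higher output of ribosomal protein transcripts in treated livers may be a candidate explanation, which was not tested.

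The spiked-in control transcripts read lower against the 75th percentile in treated livers, at 2.54 ± 0.19 (SD, n = 3) against 3.02 ± 0.04 (SD, n = 3) on the log2 scale. Treated replicate 1 on slide 1 was at 2.75, and the corn oil arrays on that slide were between 2.99 and 3.07.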
